A study of Danio rerio with 2 samples.

How the data were processed

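RNA of whole zebrafish embryos was measured on 2 Agilent zebrafish V3 arrays of the 4 x 44K format, 1 for embryos labelled igf2bp1 knockdown and 1 for control embryos. Per the labels' protocols, 1 nL of morpholino was injected per embryo, total RNA was extracted with a column kit, and Cy3-labelled cRNA was prepared from it by linear amplification. The treatment text of the control sample also names the igf2bp1 morpholino, while the design text of the series names a standard control; the group was taken from the genotype label. The labels give an age of 24 hpf and the design text 72 hpf, and neither was used to choose a result.

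Spot intensity values were made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, which subtracts the background and applies a spatial and a multiplicative detrend. The processed intensity was not normalised between the arrays, per the file headers. Flags for spots well above background, saturated spots and outliers are other columns of the deposited files and were set by the same program. The headers put both arrays on the same slide and in the same scan, so slide and scan did not differ between the groups. Probe positions are those of the files, on the Zv9 (danRer7) assembly. A deposited table of log2 values was found from its numbers to be quantile normalised: both columns have a median of 7.63, their sorted values differ by at most 0.03, and each correlates with the log2 processed intensity of its array across probes (r = 1.00). It has no centring per gene, and its direction is that of the arrays. The step that made it is not given in the sources used here.

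Of 45220 spots per array, 43803 were not controls. Spots flagged as outliers on either array were left out (23 spots), the spots of 50 probes printed 5 times were averaged, and 43595 probes remained. The value of a probe was log2 of its processed intensity minus the 75th percentile of these log2 values over the probes of its array, which was 10.08 on the knockdown-labelled array and 9.89 on the control array. The lowest signal well above background was 14.6 and 13.2. A gene was called measured where a probe was well above background on both arrays, and its value was that of the brightest such probe. Probes were named through RefSeq accessions (27850 probes), current symbols (3793) or unique synonyms (1079) in a RefSeq gene table, and the name in the file was kept for 10881 probes. This gave 26262 genes, of which 21515 (81.9%) were measured on both arrays, 14077 of them with a gene symbol, and 3868 were not well above background on either. The normalised signals in the text are scaled, whereas processed signals are printed as in the files.

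With 1 array per group no test, SE or p-value was computed. Genes were counted at a fixed threshold of 2-fold. As technical spread, the SD of the log2 difference was 0.18 between probes of the same gene and 0.20 between replicate spots (34 probes). The median of a gene list is described by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays, since genes are not replicates. The gene lists, 35 in number with 1117 of 1191 members on the array, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the igf2bp family, the 15 highest and 15 lowest genes with a symbol whose brighter signal lies above the median of detected probes and whose measured probes all lie on the same side of 0, up to 4 members of each list with the largest differences, members at least 2-fold apart where these are 6 or fewer, and the 5 largest bounds each way. Other genes named with a value, which are pah, he1.3, rho, gnat2 and prss1, were chosen after their values were seen. Lists of neural progenitor, mature neuron, immediate-early and glucocorticoid-responsive genes, 4 in number, were added after the data were seen. The 15 highest and 15 lowest named genes were left out of the last 2. Members that also belong to the fixed lists, such as atf3 and per1a, were kept. In the matching of list members to genes, 2 members matched an unrelated gene through an old synonym and were left out, also after the data were seen. The values of 1 gene and 1 list are not reported here.

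The calculation was tested on simulated data for this comparison: of 200 genes shifted by log2 values of 1.5 or 2 in either direction, 100% were recovered at 2-fold, 0 of 21285 unshifted genes passed it at a simulated noise SD of 0.21, and a list of 30 genes shifted by -0.5 had a percentile of 0 against 15.4 for an unshifted list. The simulated noise had the same SD for all probes, dim or bright. The simulation therefore checked the calculation and not how often unchanged genes pass 2-fold on these arrays. The alternatives were normexp background correction (offset 50) on the mean and local background intensity, quantile normalisation, scaling to the median or the 75th percentile of detected probes, an intensity-dependent loess curve (span 0.3), no filter on dim probes, a filter that kept the brighter probes above the median of detected probes, leaving out saturated probes, the mean over the probes of a gene, the deposited value table, and thresholds of 1.5-fold and 3-fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.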

Results

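Gene expression was measured in whole zebrafish embryos on 2 one-colour arrays, 1 hybridised with RNA of embryos labelled igf2bp1 knockdown and 1 with RNA of control embryos. Igf2bp1 is an RNA-binding protein that controls the stability, transport and translation of mRNAs in the embryo, and the series title names the growth of the early liver as its subject. A morpholino, an antisense oligonucleotide that blocks translation or splicing of its target, was injected at the 1-cell stage. The sample labels gave an age of 24 hours post fertilisation (hpf), whereas the design text of the series gave 72 hpf, and no stage was assigned here. Both arrays had 45220 spots, of which 43803 were not controls. Over the non-control spots, the median processed signal was 191 on the knockdown-labelled array and 170 on the control array. Of these spots, 84.4% and 85.3% were well above background, and none was saturated. With 1 array per group there were no replicates, so no test was made, every difference below describes these arrays, and the number of arrays limits the precision.

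The mRNA of the targeted gene, igf2bp1, was higher on the array labelled knockdown than on the control array. Its brightest probe, on chromosome 3 from 23815760 to 23815819 (Zv9), had a processed signal of 16582 against 7712, a log2 difference of 0.91 after scaling (1.88-fold). The 3 other igf2bp1 probes on chromosome 3 had log2 differences of 0.82, 0.74 and 0.58. A dim probe for an expressed sequence tag that the gene table assigns to igf2bp1, located on chromosome 4, had a difference of -0.22. The labels do not say whether the morpholino was directed at translation or at splicing, and a block of translation need not lower the mRNA, so these values did not check the label. The other family members were higher as well, igf2bp3 by a log2 difference of 0.49, igf2bp2b by 0.30 and igf2bp2a by 0.28, although the dimmest of the 3 igf2bp2a probes had -0.16. The direction of every comparison below rests on the labels, which the igf2bp1 mRNA could not check. Its higher level leaves an exchange of the arrays open.

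Genes of the differentiated liver, the exocrine pancreas and the intestine were lower on the knockdown-labelled array, together with the hatching gland genes he1.1, he1.2 and ctslb and several immediate-early genes. Genes of the cell cycle, the lens and neural progenitors were higher by smaller amounts. Of 21515 genes measured on both arrays, 157 were at least 2-fold lower and 39 at least 2-fold higher, so that 80.1% of these genes were lower, and 95.6% of all measured genes lay within 1.5-fold. Among genes with a symbol, 78 were at least 2-fold lower and 17 at least 2-fold higher. Of the 78, 14 belonged to the 10 lists of digestive organs, lipoproteins and metabolism described below, which was 5.32% of the 263 measured genes of those lists, against 0.554% of all measured genes with a symbol. The split depended on the scaling and on dim probes: 133 lower and 59 higher genes (69.3% lower) were counted after quantile normalisation, 135 and 60 (69.2%) in the deposited value table, 47 and 3 (94%) after normexp background correction, and 39 and 1 among the brighter probes alone.

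Lowest of the 15 lowest named genes was he1.1, a hatching gland protease, at a log2 difference of -2.17 (4.51-fold lower). A related protease, he1.2, was 3.48-fold lower, with 3 probes between -1.82 and -1.78, and ctslb, a cathepsin of the hatching gland, was 2.74-fold lower. Transcription factors of the immediate-early class formed a further group, with fosb 4.22-fold lower, npas4a 3.12-fold lower, egr4 2.88-fold lower, fosab 2.86-fold lower over 5 probes between -1.52 and -1.43, and ier2b 2.76-fold lower. The cytokine signalling inhibitor socs3a was 2.46-fold lower. Liver genes among the 15 lowest were uox, which encodes urate oxidase (2.76-fold lower, with probes at -1.46 and -0.37), fabp10a, the liver fatty acid binding protein (2.51-fold lower), apcs, a pentraxin (2.39-fold lower), cp, which encodes ceruloplasmin (2.37-fold lower), and g6pc1a.2, a glucose-6-phosphatase (2.36-fold lower). The 4 probes of g6pc1a.2 lay between -1.24 and -0.45. The mitochondrial carrier ucp3 was 2.47-fold lower.

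Among genes that passed the same conditions on signal and on agreement between probes, the highest had smaller differences, and none reached 2-fold. The largest were those of the lens genes crygmxl1 (log2 difference 0.91, 1.88-fold) and lenep (0.89, 1.85-fold). A Notch-responsive repressor, her12, was 1.79-fold higher. The first enzyme of haem synthesis in red cells, alas2, was 1.77-fold higher. Genes of the mitotic spindle and kinetochore were spdl1 (0.70) and cdca8 (0.55). The fin fold gene and4 had a difference of 0.64, the Notch ligand dlb 0.63, igsf9b 0.63, the proteasome subunit psmb10 0.61, zbtb20 0.58, ddx52 0.58, prdm1a 0.57 and the eye field factor six6a 0.57. The SD of the log2 difference between probes of the same gene was 0.18 over 9174 genes, and spike-in probes differed by a median of -0.05.

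**Figure D1:**
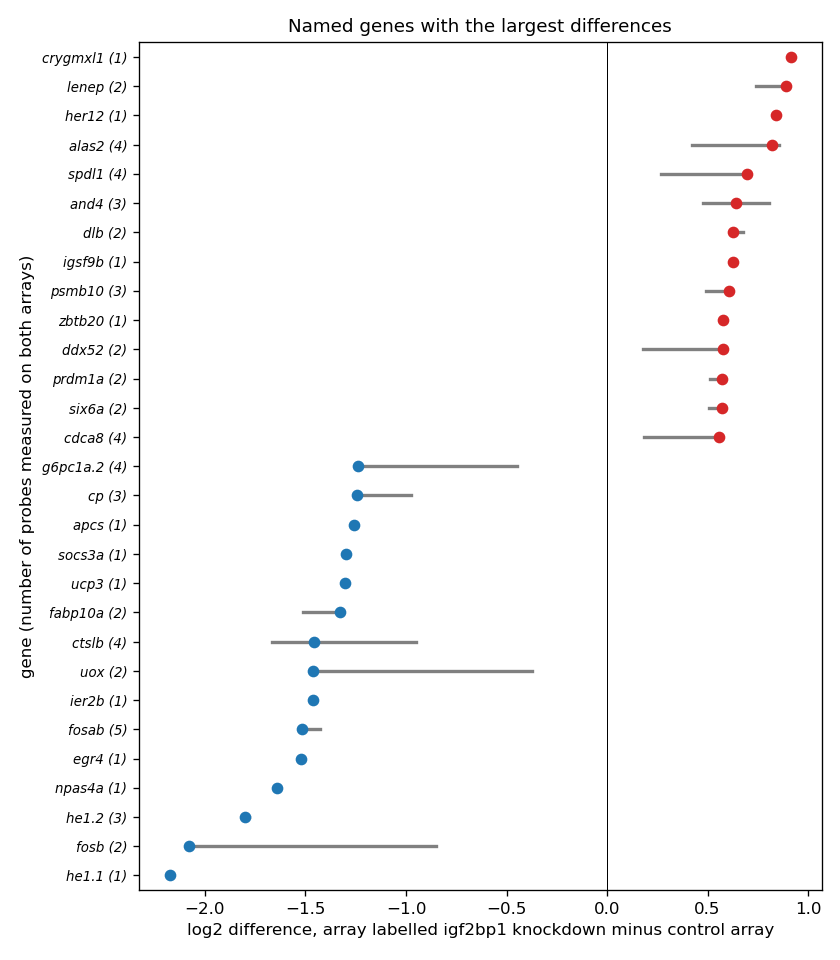
Log2 difference of 14 of the highest and the 15 lowest named genes, the array labelled igf2bp1 knockdown minus the control array, with points for the brightest probe, bars for the range over the probes measured on both arrays, and the number of these probes in brackets. The points run from 0.91 for crygmxl1 to -2.17 for he1.1, and the bar of fosb reaches from -2.08 to -0.85.

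A further 311 genes were well above background on the knockdown-labelled array alone and 568 on the control array alone. For such genes a bound is given as "at least N-fold", from the measured array's value against the higher of the dim probe's own signal and the lowest signal among probes well above background on the other array. The largest bounds among genes with a symbol were those of best1, a chloride channel of the retinal pigment epithelium, at least 8.78-fold lower on the knockdown-labelled array, smpdl3a, at least 5.75-fold lower, otofa, an otoferlin of hair cells, at least 5.03-fold lower, chrm5b, at least 4.68-fold lower, and tdrd7a, at least 4.105-fold lower. In the other direction helz2c was at least 5.23-fold higher, galnt10 at least 4.31-fold higher, arsib at least 4.01-fold higher, htra3a at least 3.92-fold higher and the endoderm factor sox32 at least 3.81-fold higher. Bounds of at least 2-fold were found for 112 genes lower and 52 genes higher on the knockdown-labelled array.

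Hepatocyte genes, which encode plasma proteins and liver enzymes, were lower almost as a whole. Of 36 measured genes 35 were lower, 7 of them at least 2-fold, and the median log2 difference of -0.76 lay below the medians of all 10000 random lists of the same size and expression. The lowest was ttr, the thyroid hormone carrier transthyretin, at -1.80 for its brightest probe and -0.88 for the other, followed by uox (-1.46), fabp10a (-1.33) and cp (-1.24). The only gene of the list that was higher was pah, at 0.03. In contrast, the transcription factors and signals of endoderm and early liver formation had a median of -0.09 (percentile 3.20 of the random lists), with 18 of 27 lower. In this group cebpd (2.07-fold lower) and cebpb (1.88-fold lower), which drive liver and acute-phase genes, stood lowest, and hnf4a had -0.55 and gata6 -0.53.

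Digestive enzymes of the exocrine pancreas had a median of -0.80, below all random medians, and 12 of 15 measured genes were lower. The elastase ela2l had the lowest value (-1.62, dim, with probes from -2.101 to -0.22). It was followed by the trypsin prss59.1 (-1.08), the lipase cel.2 (-0.97, dim) and the chymotrypsinogen ctrb.1 (-0.95). Intestinal epithelial genes had a median of -0.55, also below all random medians, with 15 of 16 lower. Among them were fabp6 (-1.09, with its other probe at -0.36), the apolipoprotein apoa4b.1 (-1.07), dgat2 (-0.77) and anpeplb (-0.71, dim). The islet list had a median of -0.25 (percentile 0.03), with 9 of 15 lower, but the median was 0.089 when only brighter probes were kept and -0.10 after normexp, inside the range of its random medians. In this list the prohormone convertase pcsk1 had -0.87, the somatostatin gene sst2 -0.57, ins -0.45 and the islet factor isl1a 0.37. Lipoprotein genes of the yolk syncytial layer and liver had a median of -0.32 (percentile 0.01; -0.20 with no filter on dim probes), with apom 2.34-fold lower, apoea 1.97-fold lower, apoc1 1.61-fold lower and apoa1a 1.55-fold lower.

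Metabolic genes were lower by smaller amounts. Gluconeogenesis and amino acid breakdown had a median of -0.26 (-0.17 among brighter probes) with 26 of 32 genes lower, including g6pc1a.2 (-1.24), g6pc1a.1 (-1.14), agxtb (-0.96) and hpda (-0.89). Glycolytic and hypoxia-induced genes had a median of -0.25 with 32 of 36 lower. These included egln3 (-0.98, with its other probe at -0.43), pfkfb3 (-0.92), ca9 (-0.68) and aldoab (-0.67). Bile acid and drug metabolism genes had a median of -0.23, with nr0b2a at -0.70, cyp8b1.1 at -0.62, slc10a1 at -0.52 (dim) and cyp1a at -0.50. Subunits of the respiratory chain and ATP synthase had a median of -0.18, and 53 of 54 were lower, the lowest being sdhda (-0.42), ndufs7 (-0.39), ndufa2 (-0.37) and sdhc (-0.34). The medians of these 4 lists lay below all random medians. The list of sterol synthesis genes and their regulators, which also holds fatty acid genes such as fads2 and scd, did not stand apart. Its median was 0.05 (percentile 87.2), where fads2 had 0.45, scd -0.38, srebf1 -0.38 and sqlea 0.34.

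Photoreceptor genes had a median of -0.37, with 37 of 43 lower and the median below all random medians. The lowest were guca1c (-0.82), the recoverin rcvrn3 (-0.73), the opsin kinase grk1b (-0.66) and the green cone opsin opn1mw1 (-0.66). Skeletal muscle genes had a median of -0.19 with 34 of 37 lower, including casq1a (-0.67), pvalb4 (-0.51), tnnt3a (-0.41) and acta1b (-0.41), and keratinocyte genes a median of -0.22 with 29 of 32 lower, including krt15 (-0.84), anxa1a (-0.56), cldnb (-0.49) and tgm1l1 (-0.47). Both medians lay below all random medians. All 13 measured heart genes were lower, with a median of -0.25 (percentile 0.105, and -0.16 among brighter probes). Their lowest values were nppa at -0.54, myh6 at -0.54, popdc2 at -0.49 and pln1 at -0.47 (dim). Leukocyte genes had a median of -0.21 (percentile 0.02), with lect2l at -0.74, lyz at -0.71, mmp13a at -0.59 and ccr9a at -0.58 (dim). Ionocyte and kidney genes had a median of -0.18 (percentile 0.08), with cdh17 at -0.52, foxi3a at -0.50, slc20a1a at -0.40 and slc12a3 at -0.31. Clock and light-responsive genes had a median of -0.21, below all random medians, with nr1d1 at -0.59, nr1d2a at -0.48, dbpb at -0.38 (dim) and tefb at -0.35.

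Proliferation genes were higher, with 42 of 45 above 0 and a median of 0.23 (1.17-fold), above all random medians. The largest values were those of cdca8 (0.55), plk1 (0.45), ccnb2 (0.43) and cdk1 (0.43), which act in mitosis. Lens genes had a median of 0.15, above all random medians, with 36 of 49 higher. Among them crygs2 had 1.07 for a dim probe and -0.15 for its other probe. For crybb2 the brightest probe had 0.75 and the other 2.16, while crygs3 had 0.44 and grifin -0.48. The neural list had a median of 0.07 (percentile 99.55), which was 0.04 and inside the range of its random medians after normexp or with the mean over probes, with members in both directions, including inab (0.45), tubb5 (0.41), sv2a (-0.54) and gad1b (-0.46).

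**Figure D2:**
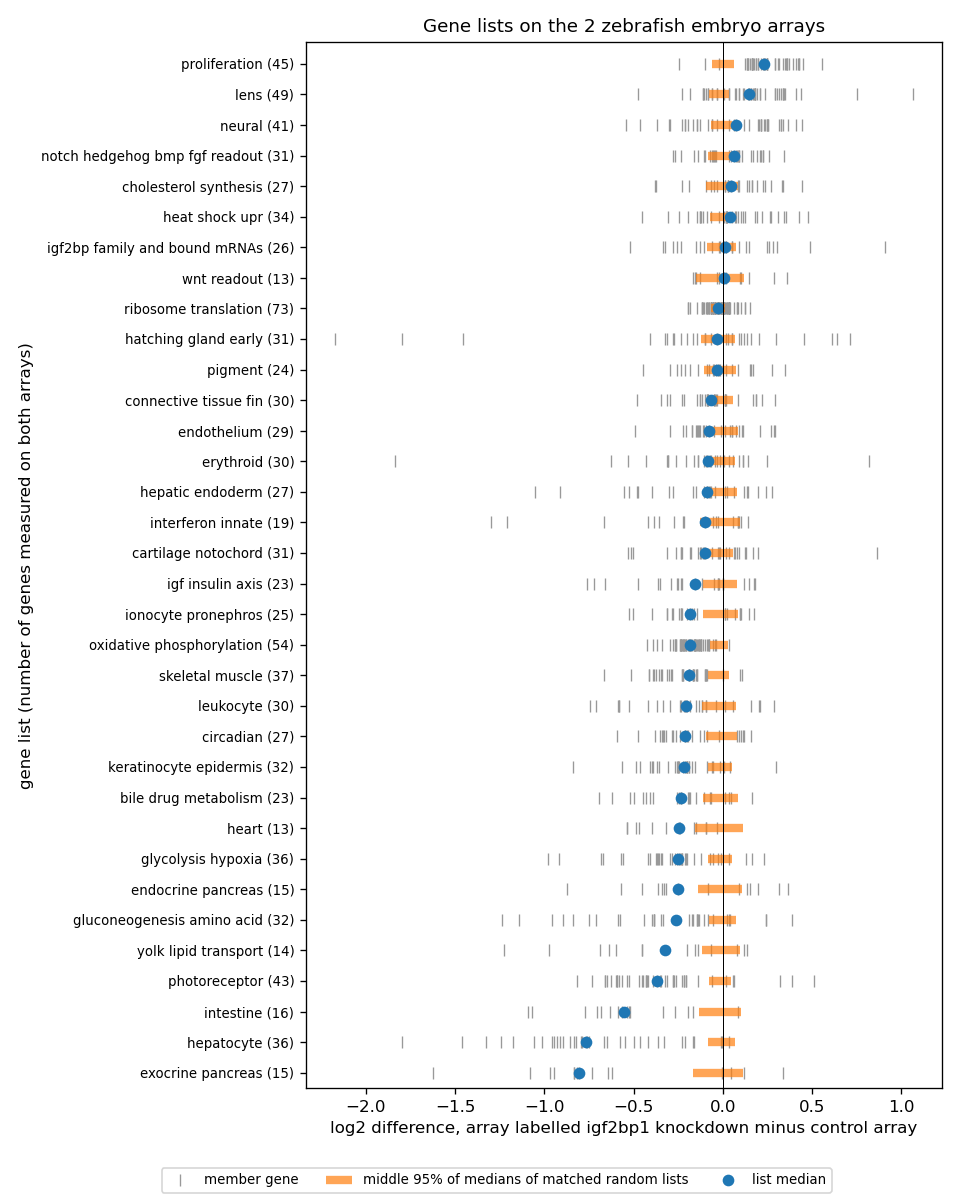
Log2 difference, the array labelled igf2bp1 knockdown minus the control array, for 34 of the 35 gene lists fixed in advance, ordered by median, with grey ticks for member genes, blue points for list medians and orange bars for the middle 95% of the medians of 10000 matched random lists. Medians run from 0.23 for proliferation to -0.80 for exocrine pancreas, and of the 34 lists drawn 18 lie below and 3 above their orange bars.

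The IGF and insulin axis had a median of -0.16 (percentile 0.33) with 17 of 23 genes lower, but -0.05 among brighter probes, inside the range of its random medians. Its lowest members were igf3 (-0.76), the translation inhibitor eif4ebp3l (-0.72) and the binding proteins igfbp1b (-0.66) and igfbp5b (-0.47). The list of the Igf2bp family and of mRNAs known in mammals to be bound by IGF2BP1 had a median of 0.01 (percentile 63.3), with 14 of 26 genes higher. Apart from igf2bp1 and igf2bp3, its largest values were those of the hyaluronan receptor gene cd44a (-0.52) and mych (-0.33). Cartilage and notochord genes had a median of -0.10 (percentile 1.29). This median lay inside the range of its random medians under 5 alternatives and was -0.01 after quantile normalisation. Lower members were hapln1b at -0.53, col10a1a at -0.52 and col8a1b at -0.50, while the notochord factor noto had 0.87 (dim).

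For 10 further lists the medians lay within the middle 95% of the random medians. The list of hatching gland enzymes and early embryonic genes had a median of -0.03 (percentile 41.1) despite the values of he1.1, he1.2 and ctslb. A further hatching enzyme in it, he1.3, had 0.13, and the early mesoderm gene ripply1 had 0.72 (dim). Red cell genes had a median of -0.08 (percentile 4.05), with the globin genes hbba2 (-1.84, dim) and hbbe2 (-0.63) and with nt5c2l1 (-0.53) lower and alas2 (0.82) higher. Interferon and innate immune genes had a median of -0.10 (percentile 7.26), with socs3a (-1.30), socs1a (-1.21), nfkbiaa (-0.66) and socs3b (-0.42) at its low end. The heat shock and unfolded protein list had a median of 0.04 (percentile 90.4), with serpinh1b (0.48), dnajb1b (0.43) and sesn2 (0.35) higher and chac1 (-0.45) lower. Endothelial genes had a median of -0.08 (percentile 3.72), with mrc1a at -0.49, aqp8a.1 at -0.30, cldn5b at 0.29 and notch1b at 0.29. Connective tissue genes had a median of -0.06 (percentile 8.32), with frem1a at -0.48 (dim), elna at -0.35, postnb at -0.31 and loxa at -0.30. Pigment genes had a median of -0.03 (percentile 31.4), with xdh at -0.45, pmelb at 0.35, tyr at -0.29 and tyrp1b at 0.28. Targets of Wnt signalling had a median of 0.01 (percentile 57.5), with ccnd1 at 0.36, nkd1 at 0.29, tcf7 at -0.16 and wif1 at -0.15. Targets of Notch, Hedgehog, BMP and FGF signalling had a median of 0.07 (percentile 96.2), with her2 at 0.34, gli1 at 0.26, dusp6 at -0.28 and spry4 at -0.27. Ribosomal proteins and translation factors had a median of -0.02 (percentile 60), and all 73 lay between rps25 at -0.19 and rps3 at 0.15, with rps28 at -0.19 and eef1a1l1 at -0.18.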

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

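All alternatives were chosen before the results were seen. No paired analysis was possible because each group has 1 array. Of the main results under the alternatives, 59 values were close to those reported and 24 moved. The value of a gene was called moved where it changed by at least the SD between probes of the same gene (0.18). For a list median the limit was that SD divided by the square root of the number of measured members, and for counts 1.5 times. Among single genes and the other lists 1925 were close, 115 moved and 1 was reversed. The reversed value was the islet list median, 0.089 with the stricter filter on dim probes. Counts of genes at least 2-fold higher and lower were 3 and 47 after normexp, 312 and 783 with no filter on dim probes, and 1 and 39 with the stricter filter on dim probes, which left 11702 genes; the count of higher genes was 59 after quantile normalisation and 60 in the deposited value table. At a 1.5-fold threshold 204 genes were higher and 741 lower, and at 3-fold 5 and 32. After normexp the medians were -0.67 for hepatocyte, -0.58 for exocrine pancreas, -0.47 for intestine, -0.30 for photoreceptor and 0.19 for proliferation genes. The photoreceptor median was -0.31 after quantile normalisation, -0.32 after loess and -0.31 in the deposited value table. With the mean over probes the igf2bp1 difference was 0.57, since its dim probe on chromosome 4 and the dimmer probes on chromosome 3 enter the mean. The medians were then -0.66 for hepatocyte, -0.64 for exocrine pancreas and -0.40 for photoreceptor genes. The cause of the other moves was not tested. Over the alternatives the hepatocyte median lay between -0.79 and -0.66 and that of proliferation genes between 0.19 and 0.25. The ribosome list had a median of -0.02 as reported and 0.05 after quantile normalisation, and the medians of the hatching, Wnt and Igf2bp lists also changed sign near 0. Leaving out saturated probes removed none and shows nothing. Signal over background limits the values of dim probes.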

Other observations

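Chosen after the results were seen were the tests of a single aberrant probe, of exchanged arrays, of sample handling, of the age on the labels and of the direction of RNA degradation, and the medians of hepatocyte genes at either end of the transcript. Of 2 added lists, neural progenitor genes had a median log2 difference of 0.22 with 31 of 37 higher, above all random medians, including rx2 (0.45), notch3 (0.44) and insm1b (0.44), while neurog3 (-0.54, dim) was lower. Mature neuron genes had a median of -0.19 with 36 of 40 lower, below all random medians, including cplx3a (-2.22, dim), gria3b (-0.56, dim), cplx4c (-0.42) and kcna2b (-0.41).

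Photoreceptor genes, which start to be expressed well after the age on the sample labels, were abundant on both arrays, with 29 of 43 above the 75th percentile of the knockdown-labelled array and 30 above that of the control array. This argues against embryos of 24 hpf on either array, without showing that they were of 72 hpf, and concerns both groups alike. The processed signal of rho was 82135 on the knockdown-labelled array and 91637 on the control array, that of gnat2 21250.3 and 24978, that of the trypsin gene prss1 2409 and 3679, and that of fabp10a 1816 and 3992.

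Genes of the liver, pancreas, intestine and photoreceptors were lower together on the knockdown-labelled array. Normalisation or background handling was argued against, since the hepatocyte median closest to 0 under another correction was -0.67. A delay of differentiation stays a candidate explanation. It needed mature neuron genes to be lower and progenitor genes higher, and their medians were -0.19 and 0.22. Both lists were added after the data were seen, and the progenitor list shares members such as neurog1 and dld with fixed lists, so this is weak support. Some lists fixed in advance had directions that a delay could give, although no prediction was made for them. Proliferation genes were higher (42 of 45), and skeletal muscle (34 of 37), heart (13 of 13) and keratinocyte genes (29 of 32) were lower. Connective tissue (median -0.06) and pigment genes (-0.03) did not stand apart from random lists. Lens genes, with a median of 0.15, went against a delay of every tissue. Hatching gland and early embryonic genes fade by larval stages and could be higher under a delay, but no stage was assigned here. Of these, he1.1 (-2.17), he1.2 (-1.80) and ctslb (-1.46) were lower. Without a stage the direction under a delay is not known, so these values argue neither for nor against it. In contrast, he1.3 had 0.13, ripply1 0.72 (dim) and the list a median of -0.03, so the list did not decide. More degraded RNA on the knockdown-labelled array would lower 5' probes more, since amplification starts at the 3' end. The 3'-most minus the 5'-most probe had a median of -0.22 (quartiles -0.31 and 0.01) over 21 hepatocyte transcripts, with -0.55 at the 5'-most and -0.77 at the 3'-most probes. This direction is the opposite one, but the criterion on direction was chosen after the value was seen, so it was no independent test. Over all 7324 transcripts with probes over 200 nt apart the median was -0.01 (quartiles -0.12 and 0.12). The planned test needed a trend of the difference along transcripts together with a large hepatocyte gap of either sign. The median over all transcripts showed no such trend, but the hepatocyte gap fell between its bounds, so the test did not decide. A direct effect of igf2bp1 on these tissues, which the design names, was not tested and stays open.

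The mRNA of igf2bp1 was higher on the array labelled knockdown. A single aberrant probe was argued against, since 4 of its probes had a log2 difference above 0.5. With arrays exchanged every difference would change sign, and with 1 knockdown array no value separates this from a higher mRNA under a block of translation. The other family members were higher as well, igf2bp3 by 0.49, igf2bp2b by 0.30 and igf2bp2a by 0.28 (its dimmest probe had -0.16). Other causes of the higher mRNA, such as the delay considered above, were not tested. The possibilities cannot be told apart.

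Immediate-early genes were among the 15 lowest named genes. An added list without the 15 highest and 15 lowest named genes had a median of -0.36 with 33 of 38 lower, below all random medians. It included rgs2 (-0.97), nr4a1 (-0.90), klf2a (-0.87) and egr2a (-0.83), so the difference may extend to the class. Glucocorticoid-responsive genes, another list with the same named genes left out, had a median of -0.31 with 23 of 28 lower. Among them were fkbp5 (-0.82), dusp1 (-0.74), lpin1a (-0.64) and rasd1 (-0.61), and the median was -0.28 without the 2 genes shared with the first list. Some members of both lists, such as atf3 and per1a, had been seen in the fixed lists. A lower response to stress hormone on that array is a hypothesis that may fit these values, and no hormone was measured. Handling of the 2 samples before RNA extraction, to which such genes respond within minutes, could give the same values, and with 1 array per group the 2 cannot be told apart.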
